A study of Homo sapiens with 4 samples.

How the data were processed

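HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, stably expressed SIRT7 with a Flag tag at passages 10 to 15. SIRT7 is a sirtuin, an NAD-dependent protein deacylase found mainly in the nucleolus. Per the labels' protocols, lysates were divided into a cytosolic and a nuclear fraction, Flag-SIRT7 was captured from each on anti-Flag gel, and the RNA that came with it was released with proteinase K, extracted and made into directional libraries. This procedure is RNA immunoprecipitation. There were 4 libraries, 2 from the cytosol and 2 from the nucleus. No input RNA and no mock immunoprecipitation were analysed here, so the values are recovered RNA and not enrichment over background. The labels number the libraries of each fraction but do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

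The deposited values are coverage: the number of reads that covered each position of an rRNA reference sequence, as a whole number that was not scaled between libraries, per the file headers and the values. One read is counted at every base it covers, so neighbouring depths are not independent counts. Per the submitters' processing notes, cutadapt 1.5, Bowtie2 2.2.6 and SAMtools were used. Their settings, the filters on reads and the use of strand are not given in the sources used here. Per the file headers, the reference sequences were 5S rRNA (121 nt, RNA5S1), the 45S precursor of the other nuclear rRNAs (RNA45SN5) and 2 mitochondrial intervals, nt 648 to 1601 and nt 1671 to 3229. The symbols of the nuclear sequences came from a RefSeq gene table. The mitochondrial intervals were named 12S and 16S rRNA by their position in the mitochondrial genome. The precursor was listed from position 8 to 13357, and positions are given below as in that sequence or counted from the first nucleotide of each rRNA. In all, 15984 positions were listed. Such a table does not separate reads from the many copies of rDNA, or mitochondrial reads from those of nuclear copies of mitochondrial sequence.

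The mature rRNAs were placed in the precursor by matching their terminal sequences. This gave the 5' external transcribed spacer (5'ETS, nt 8 to 3654), 18S (nt 3655 to 5523), internal transcribed spacer 1 (ITS1, nt 5524 to 6600), 5.8S (nt 6601 to 6757), ITS2 (nt 6758 to 7924), 28S (nt 7925 to 12994) and the 3'ETS (nt 12995 to 13357).

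Depth was expressed relative to the mean depth of the same library over all listed positions, which makes the values shares of the rRNA reads and not amounts of RNA. The means were 207648 and 197618 reads per position in the cytosolic libraries and 211717 and 189023 in the nuclear ones. Each sequence was divided into windows of 100 nt, with a last piece under 50 nt joined to the window before it. Of 161 windows, the 136 with a mean depth of at least 10 in at least 2 libraries were tested. The test was two-sided limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(relative depth + 0.01), nucleus minus cytosol, with Benjamini-Hochberg adjustment and a threshold of 0.05. A pseudocount of 0.01 of the mean stood for 1890 to 2117 reads of depth, above the depth of most spacer windows and of the cytosolic mitochondrial windows. The log2 differences of such windows are therefore far smaller than their ratios, and ratios of depth are given beside them. Regions were compared as a whole by their percent of summed depth with a two-sided exact permutation test, and by limma without a trend on log2 of the mean relative depth of the 10 regions, with no pseudocount. With 2 libraries against 2 the exact test cannot give a p below 0.333. Intervals of folds are 95% intervals of the limma fit.

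Lists of windows were tested with camera from limma, with a preset correlation of 0.01 and with an estimated one. Expansion segments are named by their textbook position and were neither aligned nor tested as a list. The lists were the windows within each region, those with at least 80% or under 50% G+C, those that hold 4 conserved elements found by sequence, and the first and last windows of each rRNA. The text names every region, the 10 windows with the largest rise and the 10 with the largest fall among windows past the threshold whose nuclear values both lie on the same side of both cytosolic values, the 5 windows of highest mean relative depth in each fraction, and the windows of the conserved elements. Tests, lists, this rule and most alternatives were fixed before the data were examined. Windows and list splits outside them are identified as such where they appear.

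The window test was tested on simulated data, with 30 of 136 windows changed in 20 draws. It recovered 86.5% of windows changed by 0.5 on the log2 scale, 99% of those changed by 1 and 100% of those changed by 2, with a mean of 0.6 false calls among 106 unchanged windows. Noise was drawn independently for each window, with the observed residual spreads shuffled over windows, and no change below 0.5 was planted. Real windows are not independent and were called at differences down to 0.0097, so these rates do not carry over to the real calls. A chi-square statistic over positions 300 nt apart was 732 per degree of freedom between the cytosolic libraries and 1159 between the nuclear ones, so neither pair was one library entered again, and all 4 were kept as separate libraries.

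Alternatives were another scaling (median of ratios, or the mean depth of 28S), windows of 50 or 200 nt, pseudocounts of 0.001, 0.1 and 0.00001, no depth filter or a minimum of 100, window medians, no variance trend, removal of a cubic in G+C, the replicate number as a block, each library left out in turn, and rRNA ends left out. When a library was left out, its fraction kept 1 library, which was assumed to vary like those of the other fraction. The cubic was fitted over all tested windows, and most of those under 50% G+C were mitochondrial. Its removal therefore cannot separate G+C content from a difference of the mitochondrial rRNAs. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.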

Results

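RNA that came down with Flag-SIRT7 from cytosolic and nuclear fractions of HEK293T cells was sequenced, and the depth of reads was given at every position of the rRNA reference sequences. The comparison between the fractions asked which rRNA sequences were recovered with SIRT7 in each compartment. Each fraction had 2 libraries. Depth summed over 15984 positions was 3319051685 and 3158724762 in the cytosolic libraries and 3384088983 and 3021350782 in the nuclear libraries, so totals were close while the median depth per position was 364.5 and 362 in the cytosol and 5322.5 and 3863.5 in the nucleus. The mature rRNAs 18S, 5.8S and 28S, which form the cytosolic ribosome with 5S, held 99.97% ± 0.00612 of the depth in the cytosol and 98.4% ± 0.115 in the nucleus (SD, n = 2). Mitochondrial 12S and 16S, the rRNAs of the mitochondrial ribosome, held 0.0236% ± 0.00537 and 1.56% ± 0.116. The transcribed spacers, which are removed from the precursor as it matures in the nucleolus and nucleus, held 0.00590% ± 0.000744 and 0.0151% ± 0.00203.

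**Figure D1:**
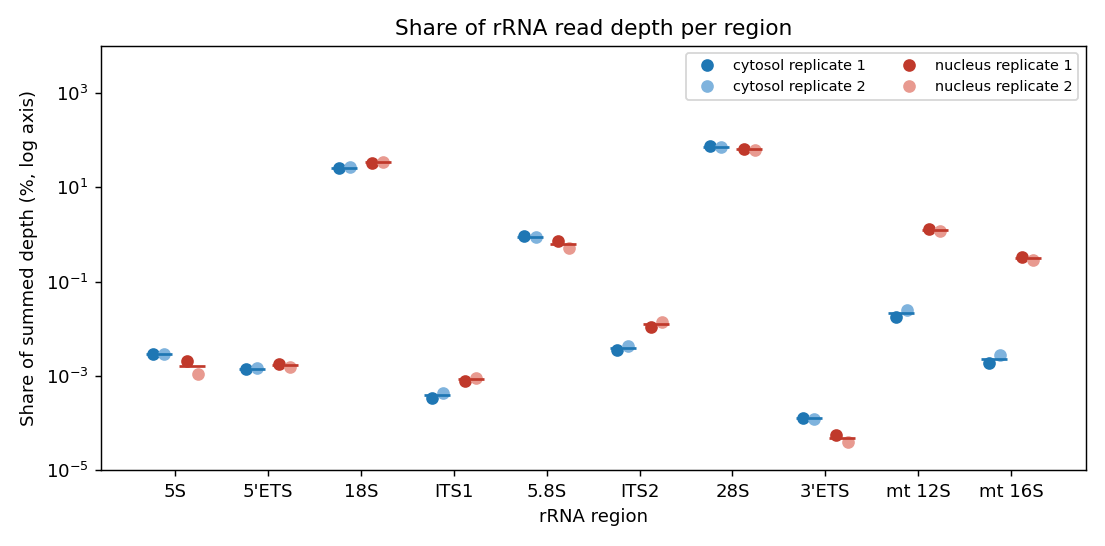
Share of summed read depth (%, log axis) held by each of the 10 rRNA regions in the cytosolic (blue) and nuclear (red) libraries, with 1 point per library and a line at the mean of each fraction. Mitochondrial 12S and 16S lie at 1.25% and 0.311% in the nucleus against 0.0213% and 0.00231% in the cytosol.

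Mitochondrial rRNA showed the largest difference between the fractions among the 10 regions. The 12S rRNA rose from 0.0213% ± 0.00479 of the depth in the cytosolic libraries to 1.25% ± 0.0800 in the nuclear ones, a 59.4-fold difference (95% interval 40.1 to 87.9, n = 2 per fraction). The 16S rRNA rose from 0.00231% ± 0.000580 to 0.311% ± 0.0358, a 136.3-fold difference (95% interval 87.8 to 211.5). Mean depth at 16S was 40.5 and 55.2 reads per position in the cytosol and 7306 and 5540 in the nucleus, so the cytosolic value rests on the thinnest data of the pair. All 10 windows of 12S and all 16 windows of 16S rose in the nucleus, by 32.3 to 71.2 times and 70.5 to 203 times in depth. With a cubic in G+C removed, all 10 windows of 12S were still higher, but of 16S 9 were higher and 5 lower. Most windows under 50% G+C were mitochondrial, so the cubic took up part of this same rise. At nt 101 to 200 of 16S, 93.7 times deeper in the nucleus, the log2 difference moved from 1.67 to -0.91. The removal therefore cannot test whether G+C content accounts for the rise. The region differences on the log2 scale were 5.89 (SE 0.21) for 12S and 7.09 (SE 0.23) for 16S, each with an adjusted p of 3.1e-05 in the limma fit.

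The 2 mitochondrial rRNAs did not rise by the same factor. Depth at 16S was lower than at 12S in every library, and the log2 ratio of 16S over 12S was -3.92 ± 0.04 in the cytosol and -2.72 ± 0.07 in the nucleus (SD, n = 2). The difference of 1.20 was larger than the spread within either fraction. The exact permutation p was 0.333, the smallest that 2 libraries against 2 allow. All 10 windows with the largest rise on the log2 scale were mitochondrial. They were the 8 windows from nt 101 to 900 of 12S, with differences of 3.60 to 4.63, and the last 2 windows of 16S, nt 1401 to 1500 and nt 1501 to 1559, with 3.17 (SE 0.09) and 2.90 (SE 0.08). Because the pseudocount exceeded the cytosolic depth of these windows, their log2 differences understate the change. At nt 1501 to 1559 of 16S the ratio of depths was 186.4. The order of the windows also differed by that ratio. It was largest at nt 1101 to 1200 (202.8) and nt 1001 to 1100 (201.8) of 16S, 2 windows outside the rule, and at most 71.2 in 12S.

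Among the spacers of the nuclear precursor, ITS2 and ITS1 rose in the nuclear libraries and the 3'ETS fell. ITS2, which separates 5.8S from 28S, rose from 0.00394% ± 0.000598 to 0.0126% ± 0.00213 of the depth, 3.18-fold (95% interval 2.16 to 4.67, n = 2 per fraction). ITS1, between 18S and 5.8S, rose 2.16-fold (95% interval 1.51 to 3.09), and the 3'ETS was 2.65-fold lower in the nucleus (95% interval 1.76 to 3.98). The 5'ETS, the long leader of the precursor, had 0.00143% of the depth in the cytosol and 0.00167% in the nucleus and did not pass the test. The adjusted p from limma was 0.00334 for ITS2, 0.00748 for ITS1, 0.00626 for the 3'ETS and 0.216 for the 5'ETS. The external spacers and ITS1 were thinly covered, with 12.5 to 16.6 reads per position in the 5'ETS, 3.31 to 11.6 in the 3'ETS and 10.6 to 25.2 in ITS1, against 100.2 and 118.2 in the cytosol and 320.5 and 364.3 in the nucleus for ITS2. The 5'ETS turned to a log2 difference of -0.53 with medians over positions (adjusted p = 0.0319) and to -0.025 with the scaling by median of ratios.

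The rise of ITS2 as a region rested on its start. The window at nt 44 to 143 of ITS2 had a relative depth of 0.00253 in the cytosol and 0.0130 in the nucleus, a 5.14-fold difference, with a log2 difference of 0.87 (SE 0.10, adjusted p = 0.00377 in limma). The next window, nt 144 to 243, was 2.50-fold higher. The remaining rise in ITS2 lay near the other end, at nt 944 to 1043, where depth was low and 2.35-fold higher (log2 difference 0.02, adjusted p = 0.0115 in limma). These 3 windows fall outside the rule for named windows and were chosen after their values were seen. When the first 200 nt of ITS2 were left out, also a choice made after the data were seen, the difference of the rest of ITS2 was 0.35 with an adjusted p of 0.209. At window level 3 of 9 ITS2 windows, 4 of 6 ITS1 windows and 3 of 19 windows of the 5'ETS rose, and 1 of 2 windows of the 3'ETS fell. The smallest called difference among these 11 windows was 0.0097 on the log2 scale, a size set by the pseudocount. Leaving out either cytosolic library left 1 rise in ITS1, and 0 calls in the 5'ETS (1 rise at an unadjusted limma p under 0.05) and in the 3'ETS (0 at that p). Without a variance trend the 5'ETS, ITS1 and 3'ETS had 0 calls (0 also at an unadjusted p under 0.05), and with a pseudocount of 0.00001 the 5'ETS had 3 rises and 4 falls.

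The depth of all spacers over that of the mature rRNAs was 2.60-fold higher in the nucleus, with log2 ratios of -13.87 ± 0.18 and -12.49 ± 0.19 (SD, n = 2, exact permutation p = 0.333). Without the first 200 nt of ITS2 the log2 difference of 1.38 dropped to 0.39. With medians over positions in place of means it turned to -0.27, so the higher ratio did not describe the typical spacer position.

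**Figure D2:**
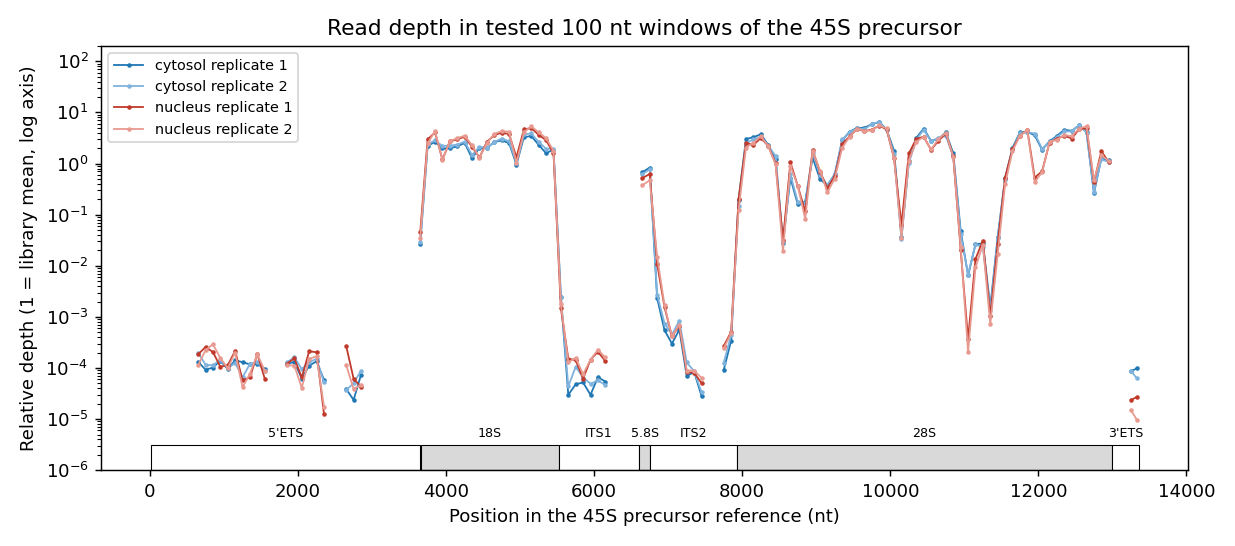
Relative depth (1 is the mean of the library, log axis) in tested windows of 100 nt along the 45S precursor, with 1 line per library, blue for cytosol and red for nucleus. Gaps are windows with too little depth to be tested, and boxes mark the regions, with the mature rRNAs in grey.

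Of the mature rRNAs, 18S held more of the nuclear depth and 28S and 5.8S less, but none of them passed the test as a whole. The 18S rRNA of the small subunit held 26.4% ± 1.60 in the cytosol and 34.1% ± 0.608 in the nucleus, and the 28S rRNA of the large subunit held 72.7% ± 1.55 and 63.7% ± 0.362 (SD, n = 2). The 5.8S rRNA, which pairs with 28S in the large subunit, held 0.907% ± 0.0529 and 0.620% ± 0.132. The 5S rRNA, transcribed outside the nucleolus by RNA polymerase III, held 0.00294% and 0.00161% ± 0.000731, and its nuclear libraries differed from each other with mean depths of 594 and 272 reads. Adjusted p-values from limma were 0.0649 for 18S, 0.216 for 28S, 0.0649 for 5.8S and 0.0667 for 5S. The adjusted p of 5S and of 5.8S from limma was 3.6e-05 and 0.00168 with the scaling by median of ratios. Leaving out nuclear replicate 1 or 2 gave log2 differences of -1.43 or -0.47 for 5S, in place of -0.95. For 5.8S the same gave -0.78 or -0.34, in place of -0.56.

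The balance between the subunit rRNAs separated the fractions. Mean depth of 28S over that of 18S was 1.02 in the cytosol and 0.688 in the nucleus, with log2 ratios of 0.02 ± 0.12 and -0.54 ± 0.03 (SD, n = 2). The difference of -0.56 exceeded the spread within each fraction, with no overlap between the libraries (exact permutation p = 0.333). The log2 ratio of 5.8S over 28S was -1.31 ± 0.05 in the cytosol and -1.69 ± 0.30 in the nucleus, a difference of -0.37 that was close to the spread of the nuclear pair. Leaving out nuclear replicate 1 or 2 moved it to -0.59 or -0.16.

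Along the rRNAs, 77 of 136 windows changed, with 53 higher and 24 lower in the nucleus. In 18S, 12 of 18 windows rose and 2 fell, and in 28S 5 of 49 rose and 20 fell. Because all values are shares, the split moved with the scaling. The median of ratios moved log2 ratios of depth by -0.24, before the pseudocount, and gave 39 higher and 33 lower, with 2 and 3 in 18S and 3 and 24 in 28S. Scaling to the depth of 28S moved them by 0.19, also before the pseudocount, and gave 61 higher and 12 lower, with 13 and 2 in 18S and 11 and 9 in 28S, so the general rise of 18S and fall of 28S describe 18S and 28S against each other. Adjusted over the list alone, 13 windows of 18S rose and 2 fell, and 5 windows of 28S rose and 19 fell. Leaving out cytosolic replicate 1 or 2 left 48 or 54 calls, with 8 or 9 falls in 28S and 0 or 2 rises (16 or 21 falls and 4 or 5 rises at an unadjusted limma p under 0.05). Once a cubic in G+C, fitted over all tested windows, was removed, 6 windows of 18S rose and 3 fell, and 19 windows of 28S rose and 14 fell. The same step made all 19 windows of the 5'ETS, 6 of ITS1, 9 of ITS2 and 2 of the 3'ETS higher and left 9 of 16 windows of mitochondrial 16S higher and 5 lower, so it also moved windows whose depth was alike in both fractions.

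**Figure D3:**
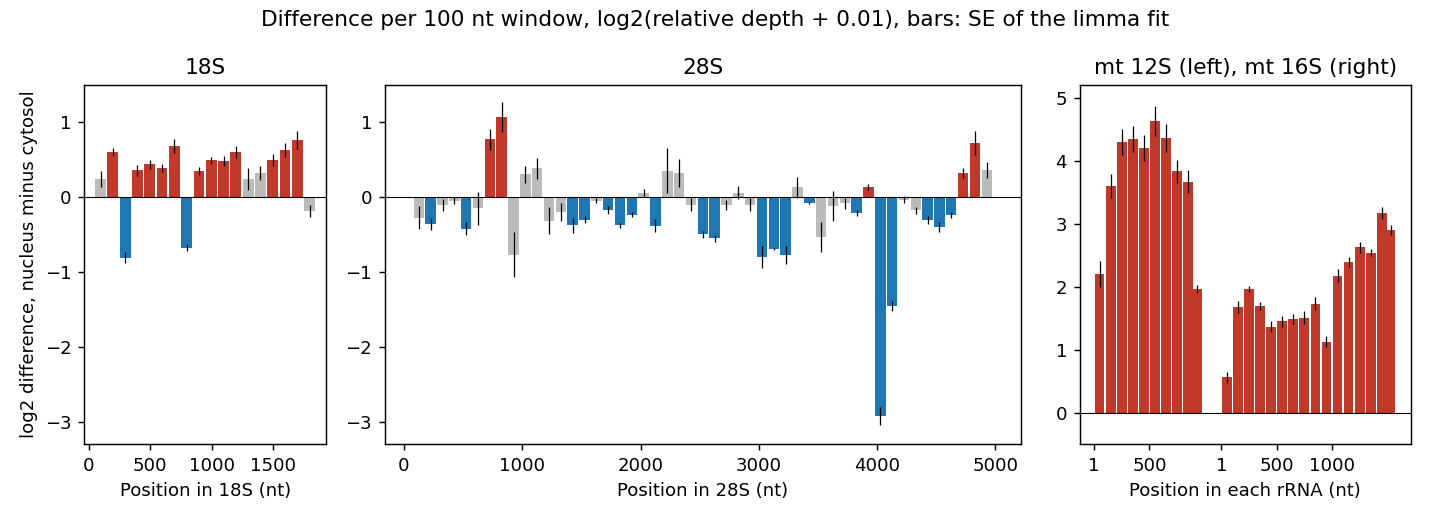
Difference in log2(relative depth + 0.01), nucleus minus cytosol, for tested windows of 100 nt within 18S, 28S and the mitochondrial rRNAs, with error bars of 1 SE from the limma fit. Red windows rose and blue windows fell past an adjusted p of 0.05, grey windows did not pass, and the largest fall, -2.92, lies at nt 3977 to 4076 of 28S.

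The largest fall on the log2 scale with the pseudocount was in a stretch of 28S toward its 3' end. At nt 3977 to 4076 the relative depth was 3.72 ± 0.214 in the cytosol and 0.484 ± 0.0637 in the nucleus (SD, n = 2), a 7.68-fold difference, and at nt 4077 to 4176 it was 1.90 ± 0.0523 and 0.690 ± 0.0242, a 2.76-fold difference. The log2 differences of -2.92 (SE 0.12) and -1.45 (SE 0.07) had adjusted p-values of 2.9e-04 and 3.6e-04 in limma. Farther ahead of the stretch, at nt 3907 to 3916, depth was higher in the nucleus, 5.75 and 5.66 against 4.98 and 4.84. Depth fell in all 4 libraries toward the stretch. Directly before it, at nt 3967 to 3976, depth was 2.47 and 2.39 in the nucleus and 2.52 and 2.83 in the cytosol. Depth then dropped to 0.356 and 0.306 at nt 3987 to 3996 in the nuclear libraries while the cytosolic ones stood at 2.10 and 2.40.

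**Figure D4:**
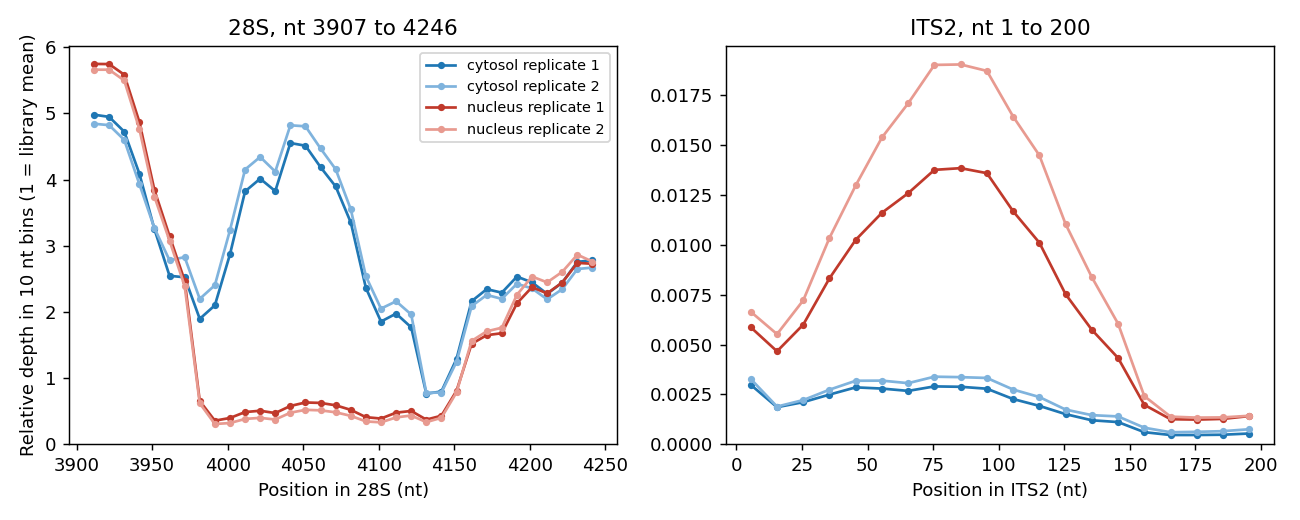
Relative depth in bins of 10 nt (1 is the mean of the library, linear axes) in 28S around nt 3977 to 4176 and in the first 200 nt of ITS2, with 1 line per library. The nuclear libraries drop from 5.75 and 5.66 at nt 3907 to 3916 of 28S to 0.356 and 0.306 at nt 3987 to 3996. Between the same bins the cytosolic libraries drop from 4.98 and 4.84 to 2.10 and 2.40. In ITS2 the nuclear libraries reach 0.0138 and 0.0190 at nt 81 to 90 against 0.00288 and 0.00336 in the cytosol.

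The other named falls were smaller on that scale, though not all by ratio of depth. A run of 3 adjacent windows of 28S from nt 2977 to 3276, within ES27L, an expansion segment (a variable part that eukaryotic rRNA has beyond the bacterial core), fell by 0.79, 0.69 and 0.77 on the log2 scale, and their G+C content was 84%, 90% and 86%. The middle window, nt 3077 to 3176, dropped from a relative depth of 0.00659 to 0.000286, which is 23.1-fold and the largest ratio among the named falls, at a depth below the pseudocount. In 18S the falls were at nt 247 to 346 (ES3S), from 2.09 ± 0.162 to 1.19 ± 0.0208, and at nt 747 to 846 (ES6S), from 2.08 ± 0.0605 to 1.30 ± 0.0146 (SD, n = 2). Their log2 differences were -0.81 (SE 0.08) and -0.67 (SE 0.05), with adjusted p-values of 0.00216 and 0.00134 in limma. The remaining named falls in 28S were nt 2577 to 2676 (-0.55), nt 2477 to 2576 (-0.50) and nt 477 to 576 (-0.42).

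These falls did not all stay past the threshold once the cubic in G+C was removed. The cubic was fitted with the mitochondrial windows, which were most of those under 50% G+C, so it took up part of their rise. At 76% G+C, as at nt 247 to 346 of 18S, its removal also moved the 5'ETS window at nt 794 to 893 from 0.02 to 0.79. A call lost here therefore cannot be assigned to G+C content. The difference at nt 247 to 346 of 18S dropped to -0.04, and those at nt 2577 to 2676, nt 2977 to 3076 and nt 3177 to 3276 of 28S to -0.02, -0.20 and -0.28, none past the threshold. At nt 477 to 576 of 28S it turned to 0.30 and passed as a rise (adjusted p = 0.0407 in limma), and at nt 2477 to 2576 it turned to 0.15 and did not pass (0.0615). The windows at nt 3077 to 3176, nt 3977 to 4076 and nt 4077 to 4176 of 28S and nt 747 to 846 of 18S stayed past it, at -0.47, -2.16, -0.82 and -0.55. Leaving out either cytosolic library ended the calls at nt 2977 to 3076 and nt 3177 to 3276 of 28S, and scaling to 28S ended that at nt 477 to 576, as did leaving out cytosolic replicate 2.

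Rises in the nuclear rRNAs reached at most 1.07 on the log2 scale. The 12 rises in 18S lay between 0.35 and 0.77, with the largest at nt 1647 to 1746. In 28S the 5 rises were at nt 677 to 776 (0.77) and nt 777 to 876 (1.07), both within expansion segment ES7L, and at nt 3877 to 3976 (0.13), nt 4677 to 4776 (0.32) and nt 4777 to 4876 (0.72). Apart from nt 547 to 646 and nt 1447 to 1546 of 18S and nt 4677 to 4776 of 28S, these windows fall outside the rule and were chosen after their values were seen. The rise at nt 777 to 876 of 28S was not even across the window. At nt 813, within it, log2 depth changed by -4.79 and -4.91 in the nuclear libraries and by -0.67 and -1.10 in the cytosolic ones. This was the steepest fall of nuclear over cytosolic depth among the scanned positions of 18S and 28S. All 5 calls in 28S ended without cytosolic replicate 1 (4 rises at an unadjusted limma p under 0.05), and 1 rise was left with window medians. The call at nt 4677 to 4776 also ended with the median of ratios, with window medians and without cytosolic replicate 2, and nt 3877 to 3976 turned to -0.06 with the cubic in G+C removed. In 18S the call at nt 1447 to 1546 ended with the median of ratios (0.25, adjusted p = 0.158) and without cytosolic replicate 1 (0.41, adjusted p = 0.0509).

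The conserved functional elements did not move together. The window of the conserved loop of helix 18 in 18S, part of the decoding centre, rose from a relative depth of 2.61 ± 0.112 to 3.43 ± 0.0994 (log2 difference 0.39, SE 0.05). The window of the sarcin-ricin loop of 28S, where elongation factors bind, fell from 5.62 ± 0.0264 to 4.77 ± 0.0784 (log2 difference -0.24, SE 0.04, SD with n = 2). Of the windows of helices 69 to 71 of 28S, which face the small subunit, nt 3777 to 3876 fell by 0.21 and nt 3677 to 3776 had -0.08 and did not pass. At the 3' end of 18S the window at nt 1747 to 1846 had -0.19 and did not pass, and the window across the boundary with ITS1 fell by 0.10, where depth lay below the pseudocount and was 1.53-fold lower in the nucleus. Adjusted p-values from limma, in this order, were 0.00706, 0.00847, 0.0138, 0.376, 0.110 and 0.00706. The helix 18 loop turned to -0.16 without the G+C trend and did not pass with the median of ratios. Scaling to 28S, or leaving out either cytosolic library, ended the calls of the sarcin-ricin loop and of nt 3777 to 3876. The boundary window turned to 0.05 with window medians and to 0.66 without the G+C trend, and its call ended without either cytosolic library, with a minimum depth of 100 and with a pseudocount of 0.00001 (-0.62, adjusted p = 0.104).

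The places of highest depth overlapped, with 3 of the 5 highest windows the same in both fractions. In both fractions the highest window was nt 1877 to 1976 of 28S, at 6.53 ± 0.0169 times the library mean in the cytosol and 5.54 ± 0.0380 in the nucleus (SD, n = 2). In the cytosol the next were nt 1777 to 1876 (5.89), nt 4577 to 4676 (5.62), nt 1577 to 1676 (4.94) and nt 1677 to 1776 (4.86), all in 28S. In the nucleus they were nt 1447 to 1546 of 18S (5.16) and nt 4677 to 4776 (5.14), nt 1577 to 1676 (4.78) and nt 4577 to 4676 (4.77) of 28S. Depth along 18S was more uneven in the nucleus, where its coefficient of variation over windows was 38.2% and 40.6% against 28.3% and 28.6% in the cytosol. For 28S the values were 81.4% and 84.7% against 81.1% and 81.3%. Mitochondrial 12S had 51.5% and 54.8% against 41.8% and 42.3%, and 16S had 62.9% and 70.5% against 37.8% and 51.3%.

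As lists, the windows of mitochondrial 12S and 16S lay above the other windows and those of 28S below them. With the preset correlation, camera gave adjusted p-values of 1.0e-05, 7.6e-07 and 8.8e-09, and each had an adjusted p of 0.671 with an estimated correlation. For 28S the other windows held the mitochondrial ones, whose rise lowers the place of any list without them. The 28S list was not tested with those windows left out. Windows with under 50% G+C were also higher, with 25 of 28 up and 1 down (adjusted p = 8.8e-09, and 0.671 with an estimated correlation), but most of them were mitochondrial. Among the 5 such windows outside the mitochondrial rRNAs, a split chosen after the data were seen, 2 rose and 1 fell (adjusted p = 0.701, and 0.811 with an estimated correlation). Of 36 windows with at least 80% G+C, 9 rose and 8 fell (adjusted p = 0.230). The other lists did not pass with camera. Their adjusted p was 0.159 for 18S, 0.701 for the 5'ETS, ITS1 and ITS2, 0.585 for the 3'ETS, 0.0920 for the 6 windows of conserved elements, of which 1 rose and 3 fell, and 0.992 for the 11 first and last windows, of which 4 rose and 1 fell. Those 4 rises were all at ends of the mitochondrial rRNAs, where every window rose, so they say nothing particular about ends.

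Profiles of log2 relative depth over the 136 windows were closer within a fraction than between fractions. Pearson's r and Spearman's rho across windows, which are not independent replicates, were 0.9996 and 0.995 for the cytosolic pair and 0.9988 and 0.998 for the nuclear pair. For the 4 pairs across fractions r was 0.943 to 0.948 and rho 0.945 to 0.955. Without the mitochondrial windows, r across fractions was 0.990 to 0.993 over 110 windows.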

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

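The pseudocount of 0.00001, the tests without mitochondrial windows or the first 200 nt of ITS2, and the crossed replicate numbers were chosen after the results were seen, and the cause of a change named here was not tested unless stated. As whole regions, the rises of mitochondrial 12S and 16S, ITS1 and ITS2 and the fall of the 3'ETS passed the limma test under every alternative run on them. The exception was ITS2 without its first 200 nt (0.35), where the removal shows that the call rested on those positions. The exact permutation p was 0.333 for each region, the smallest possible. The variance that limma shared rests on 10 regions of very unlike depth, so its adjusted p-values for regions are approximate. The 5'ETS turned to -0.53 with medians and -0.025 with the median of ratios. The latter scaling and the replicate block brought 5S (-1.19 and -0.95) and 5.8S (-0.81 and -0.56) past the threshold, with an adjusted p of 0.0473 under the block for both. Leaving out 1 library at a time gave -1.43 to -0.47 for 5S and -0.78 to -0.34 for 5.8S. The spacer ratio turned to -0.27 with medians. The 77 window calls (53 higher, 24 lower) became 146 (98 and 48) of 264 with 50 nt windows and 39 (25 and 14) of 68 with 200 nt windows, where the number of windows sets the count. There were 12 lower with scaling to 28S, 82 higher with the G+C trend removed, and 28 higher without mitochondrial windows, where 26 rising windows had been taken out. With 1 library left out there were 48 to 88 calls, 38 to 64 higher and 10 to 31 lower. A pseudocount of 0.00001 gave 94 calls (60 and 34). The replicate number as a block gave 78 calls (52 and 26) and the crossed numbers 65 (46 and 19), and same-numbered libraries deviated together with r = 0.229, a value that 2 pairs fix to be equal in both and that does not show pairing. Of 534 values of 32 named windows, 478 kept direction and side of the threshold, 42 lost the call, 3 gained one and 11 turned. In precursor positions these were 5401 to 5500 (0.00287), 9501 to 9600 (0.14), 9601 to 9700 (0.020) and 11601 to 11700 (0.11) with scaling to 28S, 5501 to 5600 (0.051) with window medians, and 4201 to 4300 (-0.16), 5401 to 5500 (0.069), 5501 to 5600 (0.66), 8401 to 8500 (0.30), 9801 to 9900 (0.020) and 10401 to 10500 (0.15) with the G+C trend removed. Mean r between fractions was 0.943 and 0.948 with 50 and 200 nt windows and 0.919 and 0.969 with pseudocounts of 0.001 and 0.1. The highest window reached 8.19 and 5.55 times the mean in the cytosol and 7.05 and 5.15 in the nucleus with 50 and 200 nt windows. For the lists, an estimated correlation raised the adjusted p of 28S, 12S, 16S and G+C-poor windows to 0.671. The 18S list passed with the block (0.0354), and the G+C-rich list with scaling to 28S (0.0335), both with the preset correlation. Without those changes each had an adjusted p of 0.811 with an estimated correlation, which was not run together with them. The direction turned for ITS2 without cytosolic replicate 1 (adjusted p 0.623 to 0.955 with 1 library left out), for G+C-poor windows outside the mitochondrial rRNAs with scaling to 28S (0.931), and for first and last windows with that scaling (0.931), with the block (0.852) and without cytosolic replicate 2 or nuclear replicate 1 (0.852 to 0.953 with 1 library left out). Leaving out positions at the highest depth was not run, since 1 position held it in each library. Depth limits the values of the 3'ETS, 5'ETS and ITS1, at 3.31 to 25.2 reads per position.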

Other observations

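The tests of mitochondrial rRNA, of runs of cytosine and of the start of ITS2 were chosen after those results were seen, while the G+C test of the 28S stretch was set before its value was known.

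Mitochondrial 12S and 16S were far higher in the nuclear libraries. The lowest log2 difference of either over 3 scalings was 5.65 (SE 0.21). The 2 other scalings moved the log2 differences of the regions by only -0.24 and 0.19, so they could not have ended a rise of this size. The choice among these 3 scalings thus did not matter for it, and other scalings were not run. The same mixture of mitochondrial RNA in both fractions was argued against, since 16S over 12S rose by 1.20 on the log2 scale with no overlap of the libraries. That value follows from the 2 region differences already seen and is no separate evidence. The cytosolic ratio rests on 40.5 and 55.2 reads per position of 16S. It cannot tell in which fraction the mixture departed, so mitochondria carried over into the nuclear fraction may still account for the rise. Association of SIRT7 with mitochondrial rRNA stays open as well, and no mock immunoprecipitation was analysed here to separate them.

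Nuclear depth dropped steeply at a few places in 18S and 28S. The steepest fall of nuclear over cytosolic depth, -3.96 on the log2 scale, was at nt 813 of 28S, within a window that rose as a whole. The next, -2.66, was at nt 3975 of 28S. For the 28S stretch at nt 3977 to 4176, with 74% and 83% G+C, the mean difference of -2.19 was still -1.49 (SE 0.07) once a cubic in G+C was removed. Both windows stayed past the threshold. That cubic also moved spacer windows of like depth and took up part of the mitochondrial rise. Its removal therefore cannot decide the part of G+C content, and -1.49 is not a measure of the part free of it. Other windows of like G+C did not fall as far as -2.92 and -1.45. The difference was 0.36 at nt 4877 to 4976 (72%), -0.38 at nt 1377 to 1476 (76%) and -0.79 at nt 2977 to 3076 (84%) of 28S. At nt 247 to 346 of 18S (76%) it was -0.81. These values argue against G+C content of the window as the whole cause. Of the 10 steepest falls of nuclear over cytosolic depth, 7 had a run of at least 4 C within the 30 nt around them, against 17.1% of 5855 scanned positions (permutation p = 3.0e-04 over 10000 draws). The draws were not matched for G+C content, and the test was chosen after the falls were seen. The p is therefore no independent support for a link to C runs. Runs of G lay at 4 of 10 falls against 21.2% (permutation p = 0.137) and runs of C at 4 of the 10 steepest rises (permutation p = 0.0769), which does not settle whether C runs are particular to falls. Cleavage, a modification or a bound structure at C-rich sites of nuclear rRNA, or a difference in library preparation between the fractions, may give such steps, and the data do not separate these.

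Nuclear depth over the start of ITS2 exceeded that of the other spacers. Reads that run past the end of mature 5.8S were argued against, since the window at nt 44 to 143 of ITS2 rose against 5.8S by 2.91 on the log2 scale and depth rose away from 5.8S, from 0.00466 and 0.00552 at nt 11 to 20 to 0.0138 and 0.0190 at nt 81 to 90 in the nuclear libraries. The start also rose against ITS2 beyond its first 200 nt, at 41.7 to 64.8 reads per position, by 2.001 on the log2 scale with no overlap of the libraries. So uneven a rise argues against carried-over rDNA or precursor with all of ITS2 as the whole cause. The window and the cut of 200 nt were chosen after this rise was seen. The values of 2.91 and 2.001 may therefore be overstated and are no independent tests. ITS2 as a whole also exceeded both external spacers by at least 1.45 (SE 0.25), but those are thinly covered, and the rise of ITS1 by 1.11 leaves room for a part played by carried-over precursor. Recovery of 5.8S precursors with a 3' extension, which are processing intermediates of the nucleus, is a candidate explanation that depth without read ends leaves open. The lower depth next to 5.8S does not favour RNA that continues from 5.8S. Depth also rose between these bins in the cytosol, from 0.00186 and 0.00189 at nt 11 to 20 to 0.00288 and 0.00336 at nt 81 to 90.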
